A study of Mus musculus with 6 samples.

How the data were processed

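RNA of 6 samples of RAW264.7 macrophages, 3 transfected with the tRF mimic and 3 with the negative control strand, was extracted 24 h after transfection with HiPerFect, per the labels' protocols. Poly(A)-selected stranded libraries were made with the KAPA kit and sequenced on an Illumina NextSeq 500, per the labels' protocols. The authors deposited a table of estimated counts per gene, which Salmon makes by sharing out reads among transcripts, and which are not scaled between libraries. FastQC, Salmon, DESeq2 and the mm10 build are named in the submitters' processing notes, with no version, and the transcript annotation and the way transcripts were summed to genes are not given in the sources used here. Between 69.4% and 71.6% of the deposited values per library are whole numbers (to within 1e-06), zeros included, and the rest are fractional. Because Salmon divides a read between similar transcripts, the values of genes with near-identical copies can move from one copy to the other without a change in expression.

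Genes are listed by Entrez Gene ID. Of 21038 IDs, 21017 were matched to a RefSeq gene table of assembly GRCm38.p6, from which symbols and coordinates were taken, and the 21 unmatched IDs hold 0.00536% of the reads. Groups and replicate numbers come from the sample titles. No pair of libraries agreed within sampling noise: a chi-square statistic per gene, near 1 for repeated sampling of 1 library, was at least 6.64 for each pair.

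Estimated counts were rounded to whole numbers. Genes were kept by filterByExpr of edgeR 4.0.16 with default settings, which left 11327 genes, and libraries were scaled by TMM. Mimic and control libraries were compared with edgeR's quasi-likelihood test with robust dispersion, with the group as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The biological coefficient of variation was 0.0824. CPM values are TMM-scaled, and log2 CPM was computed with a prior count of 2. Gene lists were written before the data were examined, 34 in all, and the 27 with at least 5 tested members were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01. Camera with an estimated correlation and fry were the alternatives. The p of fry tests whether the genes of a list move, on balance, one way and does not compare the list with other genes. R 4.3.3 was used.

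The genes named in the report follow a rule fixed before the data were examined. It takes up to 12 genes per direction among those past the threshold, filled with the smallest unadjusted p up to 5 per direction where fewer pass. It adds the 4 members with the smallest p of each list that passes and of 6 lists fixed in advance (interferon-stimulated, inflammatory, feedback, sensing, cell death and cholinergic genes), and Zbp1 always. Predicted gene models are counted and not named. In all, 0 genes passed the threshold and 47 were chosen by the rule, of which 1 is not reported here. Lars2, Sap18, Siglec1, Sdc3, Ifi204 and Gm2026 were added after their values were seen. So were Ifnb1 and the list members Ifit2 and Eif2ak2, which have a site for the mimic. Acta2, Il7r, Ebf1, Cxcr2, Kdr and Cd74 were also added, as the most abundant members of lists not tested in the main fit.

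For the seed test, the longest protein-coding transcript of each gene with a 3' UTR was taken from GENCODE mouse release 21, also on GRCm38, and 172 tested genes without an annotated 3' UTR were not searched. The difference in mean log2 fold change between genes with and without the word was ranked among 7-base words whose number of site genes was within 1.5 times. Sharing of sequence was measured as the percent of a gene's distinct 31-base words found in transcripts of other genes. Python 3.11.15 was used for these steps.

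The tests were run on simulated data first. For the mimic against the negative control, counts were drawn 5 times for 11277 genes tested, with 200 genes changed. The edgeR test recovered 23.4% of genes changed by 1.25-fold, 77.7% by 1.5-fold, 93.1% by 2-fold and 99.2% by 4-fold, with 8.4 false calls per simulation. The simulated libraries had no axis of variation beyond the group. Camera called a list of 50 genes shifted by -0.15 in 5 of 5 simulations and 0 of 100 unshifted lists, again without correlation between genes. The seed test found a planted shift of -0.05 in 20 of 20 simulations of 11155 genes. The noise there was independent between genes and had no trend with sequence, so the test may find less in these libraries.

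Alternatives fixed before the data were examined were DESeq2 size factors, library totals, no filter, a filter of CPM above 1 in 3 libraries, unrounded counts, DESeq2 1.42.0, limma-voom, the replicate number as a block, other thresholds, other sites and regions for the seed test, and leaving out each library in turn. A fit with 1 surrogate variable from sva 3.50.0, fry with that variable, and seed words matched for G and C were added after seeing the data.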

Results

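Messenger RNA was measured in RAW264.7 cells, an established mouse macrophage line, after transfection with a short synthetic RNA. The mimic copies tRF-22-WE8SPOX52, a fragment of a transfer RNA, and was supplied as a single 5'-phosphorylated strand at 50 nM. The comparison group received the strand NC5 as negative control, at a dose the labels do not give. Cells were collected 24 h after transfection. There were 3 mimic libraries and 3 negative control libraries, and no untransfected cells were analysed here. The series places the fragment among regulators of a cholinergic immune blockade after stroke, and the comparison asks which macrophage transcripts differ once the mimic is present. The labels do not say whether the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Library totals, rounded to 6 digits, were 27257400, 24151400 and 28166100 estimated reads for mimic replicates 1, 2 and 3, and 23531600, 30484300 and 34014400 for negative control replicates 1, 2 and 3.

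The libraries resembled each other closely, with Pearson correlations of log2 CPM between 0.990 and 0.996 across the 11327 genes tested. Their largest axis of variation did not follow the transfection. The first principal component held 40.5% of the variance of the 500 most variable genes and placed mimic 1, negative control 1 and mimic 3 on one side and the other libraries on the opposite side. Lars2, the mitochondrial leucyl-tRNA synthetase gene, varied by 61.9-fold between libraries, at 4694, 6865 and 175 CPM in mimic replicates 1, 2 and 3 and 3080, 10863 and 629 CPM in negative control replicates 1, 2 and 3. Lars2 was singled out after its values were seen.

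**Figure D1:**
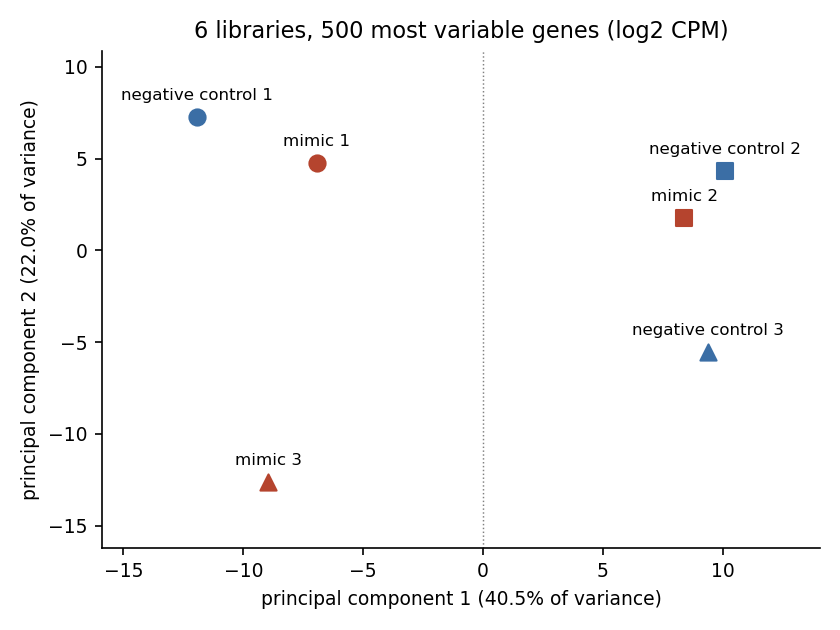
Principal components 1 and 2 of the 6 libraries, from log2 CPM of the 500 most variable genes, with color for the transfected strand and marker shape for the replicate number. Each side of component 1, which holds 40.5% of the variance, has libraries of both groups.

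No single gene passed the test over all genes, and of the 137 genes with an unadjusted p under 0.05, 99 were lower with the mimic. Zbp1, which encodes a sensor of Z-form nucleic acids that can trigger necroptosis, was lower with the mimic, with a fold change of 0.757. Oasl2, an oligoadenylate synthetase-like antiviral gene, had a log2 fold change of -0.30 (SE 0.058), and Apol9b, an apolipoprotein L family gene, one of -0.45 (SE 0.10). Amn1, a gene with low expression here, stood at 3.66 ± 0.296 CPM with the mimic and 5.31 ± 0.297 CPM with the control (SD, n = 3 each). Among genes that were higher, Lgalsl, a galectin-like gene, had a log2 fold change of 0.22 (SE 0.072), Mtx3, a metaxin of the mitochondrial outer membrane, 0.23 (SE 0.077) and Ankrd9, an ankyrin repeat gene, 0.42 (SE 0.14). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 0 of 11327 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.9998. The 137 genes at an unadjusted p under 0.05, 99 lower and 38 higher, are fewer than the 566 that chance alone gives. DESeq2 called 2 genes, Sap18b and Zbp1, both lower, and limma-voom called 0. Without mimic replicate 2, edgeR called 1 gene, the predicted gene model Gm2026, which was named after its value was seen.

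The largest fold changes among these genes belonged to near-copies of other genes and to very low counts. Sap18b was at 0.285 ± 0.124 CPM with the mimic and 2.61 ± 1.78 CPM with the control (SD, n = 3 each), a log2 fold change of -3.20 (SE 0.60), and 98.8% of its 31-base words also occur in Sap18. Zfp965, a zinc finger gene, was at 0.634 ± 0.124 CPM with the mimic and 0.0293 ± 0.0508 CPM with the control, and 97.9% of its words occur in other genes. Its control value rests on 3.02 estimated reads in negative control replicate 3, with 0 in the others, and without that library its log2 fold change moved from 4.05 to 7.08. Tmem254a stood at 0.914 ± 0.405 CPM with the mimic and 0.14 ± 0.13 CPM with the control, with 72.9% of its words shared. Reads of these genes, and of Apol9b (64.9% shared), can be assigned to a relative, so their values are uncertain.

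Zbp1 was fixed for testing before the data were examined, because it is remembered as a gene the study followed up. The study may have picked it from these same libraries, so its test here is not independent of them. It was lower in each mimic library than in any control library. The gene lies on chromosome 2 from 173206612 to 173218959 in GRCm38, the assembly also called mm10. Its log2 CPM was 5.03, 4.97 and 5.08 in mimic replicates 1, 2 and 3 and 5.54, 5.35 and 5.39 in negative control replicates 1, 2 and 3. Between 757 and 1431 estimated reads per library stand behind these values. The mean was 32.5 ± 1.32 CPM with the mimic and 43.0 ± 2.91 CPM with the control (SD, n = 3 each), a log2 fold change of -0.40 (SE 0.072). The unadjusted p of edgeR's quasi-likelihood test was 0.000417, and after adjustment over all 11327 genes it was 0.9998. DESeq2 gave an adjusted p of 0.0418. An exact two-sided permutation test of log2 CPM gave p = 0.1, the smallest that 3 libraries against 3 can give.

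Type I interferon-stimulated genes, the antiviral program that interferon alpha and beta switch on, fell as a group. Of 54 measured members, 50 were lower with the mimic, and the median log2 fold change was -0.16, or -10.2%. Besides Zbp1 and Oasl2, Ddx60, a helicase that promotes antiviral signalling, was at 25.3 ± 0.0376 CPM against 30.3 ± 1.29 CPM, and Irf7, the transcription factor that amplifies interferon production, at 442 ± 8.77 CPM against 521 ± 36.2 CPM (mimic against control, SD, n = 3 each). In 27 members the 3 mimic libraries all lay below the 3 control libraries, and over all genes such complete separation in either direction occurred in 4.79%, where chance gives 10%. Averaged over the list, log2 CPM lay 0.16 below the control mean with the mimic, at -0.10, -0.19 and -0.20 in replicates 1, 2 and 3, while the control replicates lay between -0.01 and 0.01. An exact permutation test of these list means gave p = 0.1, the smallest possible. The competitive camera test of limma, with a preset correlation of 0.01 and adjusted over 27 lists, gave an adjusted p of 2.07e-39. With an estimated correlation the adjusted p was 0.0595, and the rotation test fry gave 0.0497. There were 23 members at an unadjusted p under 0.05, all lower, and 2 passed when adjusted over the list alone, Zbp1 and Oasl2, against 0 over all genes tested. In the 9 other ways of parting the libraries 3 against 3, camera with the preset correlation called between 1 and 10 lists. Each puts both groups on both sides, and the split along the first principal component is among them, so these calls need not be false. The correlation estimated for this list was 0.088, above the preset 0.01, which makes the preset adjusted p too small here. The correlation need not be the only reason for the rise to 0.0595. For the necroptosis and pyroptosis list the estimate was -0.039, below the preset. Yet the adjusted p of camera for that list rose from 0.0065 to 0.326 with the estimated correlation. The estimates were also above the preset for MHC class I (0.425), histones (0.235), cholesterol (0.181) and endoplasmic reticulum chaperones (0.0642). The preset adjusted p of these lists, and of other lists with a high estimate, may be too small as well.

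**Figure D2:**
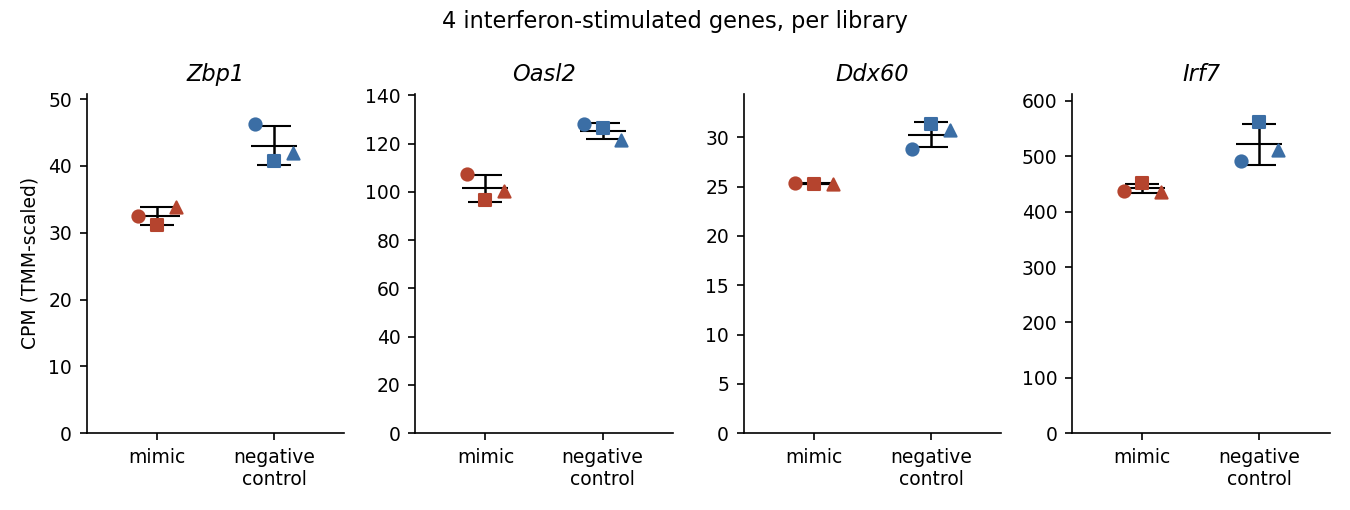
CPM of Zbp1, Oasl2, Ddx60 and Irf7 in each library (TMM-scaled, linear axes from 0), with marker shape for the replicate number and black bars for the group mean and SD over 3 libraries. In each panel the 3 mimic libraries lie below the 3 negative control libraries.

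Genes of MHC class I antigen presentation, which load and display peptides to T cells, fell as a group, with 19 of 21 measured members lower and a median log2 fold change of -0.12. H2-T23, a nonclassical class I gene, had a log2 fold change of -0.16 (SE 0.064), H2-T24 one of -0.15 (SE 0.064), H2-Q4 one of -0.11 (SE 0.051) and Tapbp, the tapasin of the peptide-loading complex, one of -0.12 (SE 0.058). None of them passed alone, and 24.5% of the 31-base words of H2-T23 and 38.4% of those of H2-Q4 are shared with other genes. Camera gave an adjusted p of 4.18e-09, and the adjusted p was 0.399 with an estimated correlation. The list mean of log2 CPM, relative to the control mean, overlapped between groups, at -0.12, -0.02 and -0.20 in mimic replicates 1, 2 and 3 and -0.13, 0.11 and 0.02 in negative control replicates 1, 2 and 3 (exact permutation p 0.3). This list also differed along the first principal component, where its median log2 fold change was -0.17 for mimic 1, negative control 1 and mimic 3 against the other libraries. Its median for the mimic moved to -0.06 without negative control replicate 2 and to -0.18 without negative control replicate 1.

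The necroptosis and pyroptosis machinery, the genes of 2 lytic forms of cell death, fell by a small amount, with 15 of 20 members lower and a median log2 fold change of -0.05. Zbp1 is the member this list shares with the interferon-stimulated list. Mlkl, the pore-forming executor of necroptosis, was at -0.11 (SE 0.071), Adar, an RNA-editing enzyme that restrains Zbp1, at -0.09 (SE 0.071) and Casp1, the inflammatory caspase, at -0.09 (SE 0.066), all as log2 fold changes that did not pass alone. Camera gave an adjusted p of 0.0065, which became 0.326 with an estimated correlation. The list mean lay lower in each mimic library than in any control library (exact permutation p 0.1). Without Zbp1, 19 members had a median of -0.04 and an unadjusted camera p of 0.0178. The call ended without negative control replicate 1 (adjusted p = 0.0692) and without negative control replicate 3 (adjusted p = 0.0582), both by camera. Within the list alone, 1 member passed, which was Zbp1.

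Genes of cholesterol synthesis and uptake rose as a group, with 20 of 24 measured members higher and a median log2 fold change of 0.10, or 7.37%. Hmgcs1, which makes the substrate of HMG-CoA reductase, was at 126 ± 8.87 CPM with the mimic and 113 ± 6.9 CPM with the control. Sqle, the squalene epoxidase, was at 153 ± 5.15 against 140.3 ± 7.41 CPM, Msmo1, a sterol demethylation enzyme, at 161 ± 1.78 against 149 ± 4.04 CPM and Lss, the lanosterol synthase, at 83.9 ± 1.2 against 77.4 ± 4.05 CPM (mimic against control, SD, n = 3 each). In these 4, picked for the smallest p, no mimic library overlapped a control library, as in 6 of the 24 members, and none passed alone. The list mean of log2 CPM, relative to the control mean, overlapped between groups, at 0.02 in mimic replicate 1 and 0.05 in negative control replicate 2 (exact permutation p 0.2). Camera gave an adjusted p of 2.69e-07, and the adjusted p was 0.361 with an estimated correlation. Without negative control replicate 1 the median was 0.04 and camera's adjusted p was 0.0813, and without mimic replicate 2 the median was 0.07, where the call held.

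Endoplasmic reticulum chaperones and unfolded protein response genes rose slightly, with 19 of 21 measured members higher and a median log2 fold change of 0.04. Dnajc3, an Hsp40 co-chaperone of the reticulum, had a log2 fold change of 0.11 (SE 0.053), Sel1l, an adaptor of reticulum-associated degradation, 0.07 (SE 0.047), Manf, a secreted reticulum stress factor, 0.07 (SE 0.058) and Canx, the lectin chaperone calnexin, 0.07 (SE 0.063), with none passing alone. Camera gave an adjusted p of 0.00118, which became 0.361 with an estimated correlation. The list mean overlapped between groups (exact permutation p 0.2). Without mimic replicate 3 the median was 0.03 and camera's adjusted p was 0.0567. The median was 0.07 without mimic replicate 2 and 0.07 without negative control replicate 1, and there the call held.

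Genes of the histone list were lower in 17 of 20 measured members, with a median log2 fold change of -0.24. Most of them are replication-dependent, with transcripts that mostly lack the poly(A) tail that these libraries select for. H4c8 had a log2 fold change of -0.92 (SE 0.51), H1f2 one of -0.11 (SE 0.11), H4c1 one of -0.93 (SE 0.96) and H2ac18 one of -0.28 (SE 0.31), and none passed alone. H4c8 and H4c1 were below 1 CPM in both groups, and 50% and 47.9% of their 31-base words, and 89.8% of those of H2ac18, are shared with other genes. The list fell by camera with an adjusted p of 0.0411, which became 0.79 with an estimated correlation. The list mean overlapped between groups (exact permutation p 0.4). The call ended without negative control replicate 1 (adjusted p = 0.375), negative control replicate 2 (adjusted p = 0.689) or mimic replicate 3 (adjusted p = 0.513), and it ended with 1 surrogate variable in the fit, an alternative added after seeing the data (adjusted p = 0.094). The median was -0.05 without negative control replicate 2, -0.13 without mimic replicate 3, -0.14 without mimic replicate 1, -0.38 without mimic replicate 2 and -0.54 without negative control replicate 3.

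**Figure D3:**
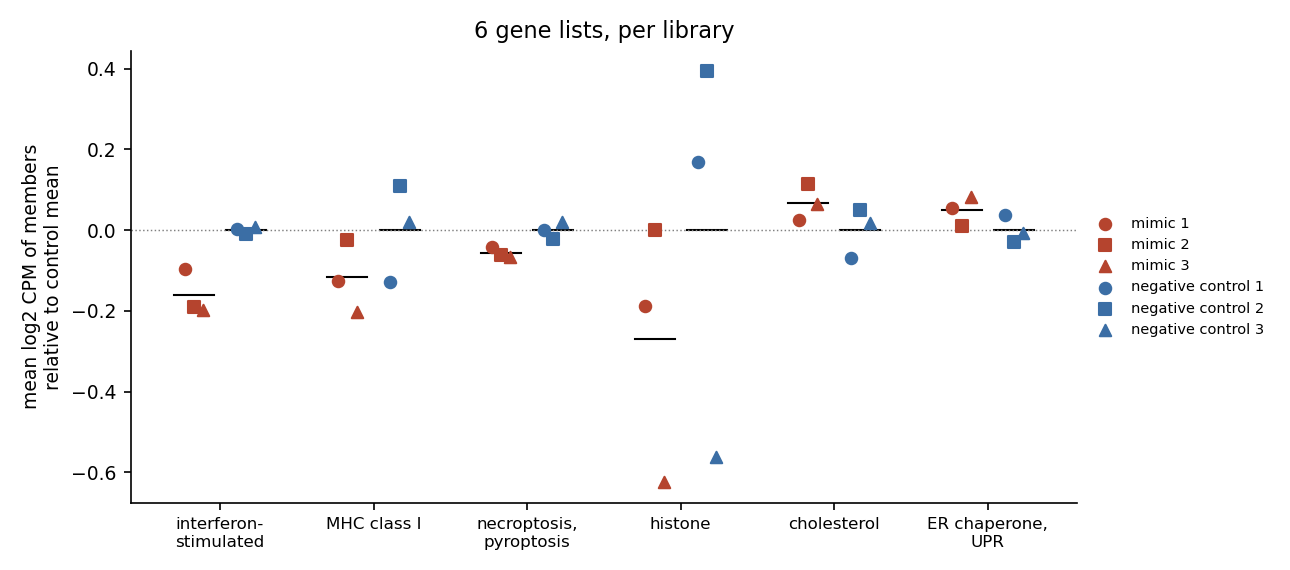
Mean log2 CPM of the members of each of 6 gene lists in each library, relative to the mean of the 3 negative control libraries, with color for the group, marker shape for the replicate number and black lines for group means. The interferon-stimulated list lies between -0.20 and -0.10 in the mimic libraries and between -0.01 and 0.01 in the controls, while histone genes spread more within each group than between them.

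Inflammatory output, the signalling that restrains it, nucleic acid sensing and cholinergic genes did not pass. NF-kB-driven cytokines and chemokines had 14 of 21 members lower, a median log2 fold change of -0.04 and a camera adjusted p of 0.322. With each library left out, that median lay between -0.07 and -0.02, without a camera call. Of the members of this list, Ccl4, a chemokine for monocytes and T cells, was at -0.14 (SE 0.11) and Acod1, which makes itaconate, at -0.11 (SE 0.088). Il27 was at 0.58 (SE 0.39) and Ccrl2 at 0.46 (SE 0.27). Feedback inhibitors of inflammatory signalling had 17 of 28 members lower, a median of -0.02 and a camera adjusted p of 0.322, with Dusp1 and Dusp5, which encode MAP kinase phosphatases, at -0.10 (SE 0.072) and -0.09 (SE 0.07), and Sbno2 and Trib1 both at -0.09 (SE 0.073 and SE 0.074). Nucleic acid sensors and Toll-like receptor signalling genes had 16 of 33 members lower, a median of 0.00 (mean -0.02) and a camera adjusted p of 0.727. Nod1 was at -0.37 (SE 0.24), Pld3 at -0.08 (SE 0.055), Ikbke at 0.14 (SE 0.11) and Tlr4, the endotoxin receptor, at 0.12 (SE 0.091). Of 36 cholinergic receptor, enzyme and transporter genes, 12 were expressed enough to test, with 7 lower and a camera adjusted p of 0.727. Slc44a1, a choline transporter, was at 0.08 (SE 0.052), Chrnb2, a nicotinic receptor subunit, at -0.08 (SE 0.083) and Chkb, a choline kinase, at -0.08 (SE 0.085), with 47.9% of the words of Chkb shared. All values are log2 fold changes of the mimic against the control.

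Together with these, 21 of the 27 tested lists did not pass, with camera adjusted p between 0.106 and 0.763 and medians between -0.04 and 0.03 on the log2 scale. They include ribosomal protein, oxidative phosphorylation, cell cycle, p53 target, ATF4 target, NRF2, heat shock, lysosome, glycolysis, macrophage identity, alternative activation, osteoclast, lipid synthesis, immediate-early, small RNA silencing and extracellular protease genes. The list mean of alternative activation genes lay higher in each mimic library than in any control library (exact permutation p 0.1). Camera's adjusted p for that list was 0.106, and its median of 0.03 moved to 0.09 without mimic replicate 3. Of these 21 lists, 6 were called by camera with a library left out or with 1 surrogate variable, the alternative added after seeing the data. NRF2 oxidative stress genes had a median of -0.03, and camera called them lower without mimic replicate 1 (median -0.08, adjusted p 7.89e-07), without negative control replicate 2 (-0.07, 7.91e-05) and with the surrogate variable (-0.03, 0.0282). Lysosome and phagocytosis genes were called lower by camera in the same fits (adjusted p 0.0073, 0.00138 and 0.0282). Ribosomal protein genes were called lower by camera without negative control replicate 1 (adjusted p 0.000421) and without mimic replicate 2 (0.00223), with a median of -0.08 in both, and higher with the surrogate variable (0.02, adjusted p 0.0127). Camera also called fatty acid synthesis and LXR target genes higher without mimic replicate 1 and without negative control replicate 2, heat shock genes higher without negative control replicate 1 and without mimic replicate 2, and G2 and M phase genes lower without mimic replicate 3, with adjusted p between 0.00138 and 0.0388. Of the fibroblast, T and NK cell, B cell, neutrophil and mast cell, and epithelial, endothelial and erythroid lists, 1, 2, 2, 3 and 1 genes could be tested. Their most abundant members were Acta2 at 1.61, Il7r at 17.95, Ebf1 at 71.7, Cxcr2 at 3.1 and Kdr at 0.895 mean CPM, and their unadjusted p in edgeR lay between 0.243 for Kdr and 0.731 for Ebf1. MHC class II genes had 4 testable members, led by Cd74 at 66.7 mean CPM. Of the mitochondrially encoded list 0 genes were in the table. These 7 lists were therefore not tested in the main fit. Without the filter on low counts, camera tested all of them but the mitochondrial list, with adjusted p between 0.466 and 0.867.

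**Figure D4:**
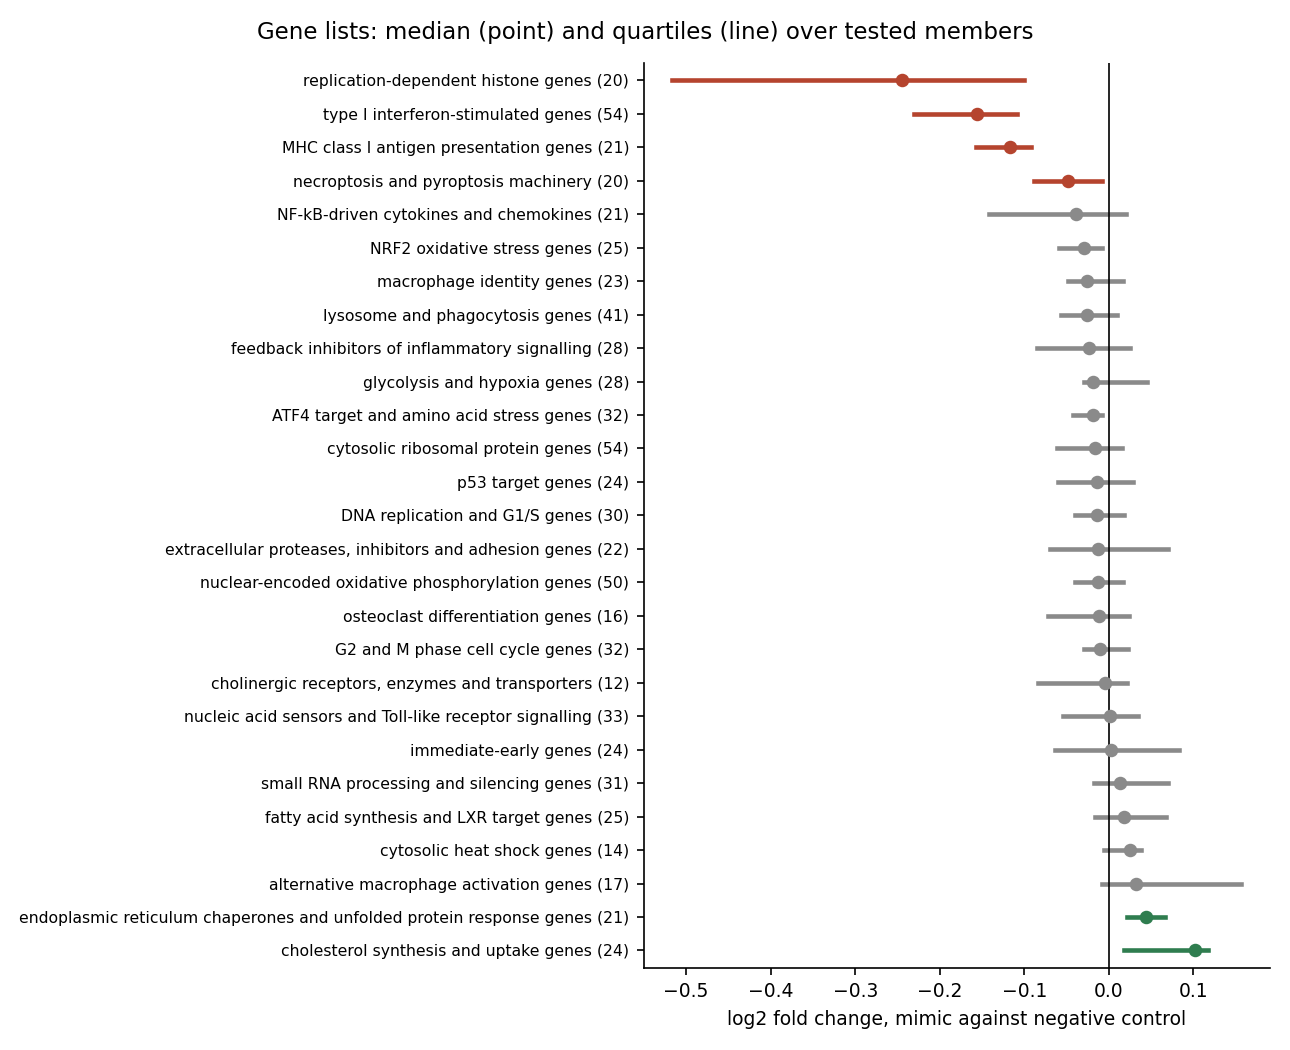
Log2 fold change of the mimic against the negative control for each of 27 gene lists, as the median over tested members (point) and the quartiles (line), with the number of tested members in parentheses. Red and green lists fell and rose by camera with a preset correlation of 0.01, and gray lists did not pass. With an estimated correlation 0 of the 27 lists pass.

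Genes with a site for the mimic did not fall together. The mimic, AUCCCACCGCUGCCACCA as the labels write it, has 18 bases, fewer than the length in its name. The reverse complement of its bases 2 to 8 is GGTGGGA. This word occurs in the annotated 3' UTR of 1617 of the 11155 genes searched, and their mean log2 fold change differed from that of the other genes by 0.00848. That difference had a two-sided percentile p of 0.523 among 6285 other words with similar numbers of site genes. Among 742 of these words matched for G and C, a choice made after seeing the data, the p was 0.108, and the percentile counted from the low end moved from 26.2 to 94.8. For the negative control strand, whose site is ATAGTCG, 88 genes had a site, with a difference of 0.0212. Its rank among 1074 words corresponded to a two-sided percentile of 0.51. The 605 bases of the Zbp1 3' UTR hold 0 of the mimic's 7-base sites and 1 match to the 6-base site, GTGGGA. If the transfected strand began at another base than the labels give, these sites would be others.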

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

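The fits with 1 surrogate variable, fry with that variable and seed words matched for G and C were chosen after seeing the data. The count of 0 genes for the mimic against the negative control also held in edgeR with DESeq2 size factors, library totals, either filter, unrounded counts, an adjusted p of 0.1 or a log2 fold change of at least 1, and in limma-voom. It was 2 with DESeq2 (Sap18b and Zbp1), 1 with the replicate block (Sap18b), 7 with 1 surrogate variable, and 0 to 1 when each library was left out, with Gm2026 called without mimic replicate 2. Zbp1 passed with DESeq2 (log2 fold change -0.40, adjusted p 0.0418) and with 1 surrogate variable (-0.43, adjusted p 0.000629). Its log2 fold change lay between -0.44 and -0.35 over 15 alternatives, with adjusted p between 0.0418 and 1 over those fixed in advance. The replicate numbers were not taken to pair the libraries: deviations from the group means correlated at 0.18, 0.43 and -0.08 for numbers 1, 2 and 3, and negative control 1 correlated best with mimic 3 (0.34). Whether the numbers mark a shared origin stays open. In the deposited column names the mimic and control libraries of a number share a letter, whose meaning is not given. Lars2 ranked the numbers alike in both groups. It was lowest in number 3 (175 CPM with the mimic, 629 CPM with the control) and highest in number 2 (6865 and 10863 CPM). The second principal component was negative in the libraries of number 3 alone (-12.6 and -5.52). The block left 6 lists called and changed no list's call. Camera's adjusted p for the histone list was 0.000148 with the block, against 0.0411 without it. The exact permutation tests do not use the replicate numbers.

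Of the 6 lists that passed camera, 0 passed with an estimated correlation, 2 with fry (the interferon-stimulated and the necroptosis and pyroptosis lists) and 0 by fry with 1 surrogate variable. The adjusted p of the interferon-stimulated list was 0.0595 with an estimated correlation (0.154 with the surrogate variable as well) and 0.0649 by fry with the surrogate variable. In the same order, and with fry alone in between where the call ended there, the values were 0.326 and 0.0649 for necroptosis and pyroptosis, 0.361, 0.692 and 0.134 for cholesterol, 0.361, 0.587 and 0.0649 for reticulum chaperones, 0.399, 0.736 and 0.0649 for MHC class I, and 0.79, 0.909 and 0.915 for histones. The histone list was also at 0.094 in camera with the surrogate variable. With each library left out, camera's adjusted p lay between 0.00112 and 0.0692 for necroptosis and pyroptosis, 4.39e-12 and 0.0813 for cholesterol, 0.00252 and 0.0567 for reticulum chaperones, and 3.56e-11 and 0.689 for histones. The interferon-stimulated and MHC class I lists stayed called in each of these 6 fits.

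The seed difference turned to -0.00119 in coding sequence and passed in no setting. Its two-sided percentile p was lowest without negative control replicate 2 (0.0617, toward higher values) and was 0.108 among words matched for G and C. It ranged from 0.00157 to 0.0136 when each library was left out, and that of the control strand from -0.00429 to 0.0477 when each library was left out. Of 771 values under the alternatives, 756 kept their direction and side of the threshold, or a similar count of lists. None of the genes passed in the main fit, so a kept side means only that a gene still did not pass. Of the rest, 8 came to pass the threshold and 4 turned direction. The others were counts of called lists, which fell with an estimated correlation, with fry and by fry with the surrogate variable. The 771 values cover the number of lists called, Lars2, Sap18, Siglec1, Sdc3, Ifi204 and the genes chosen by the rule, apart from Zbp1. H4c1 ranged from -2.90 to 0.15, H2ac18 from -0.57 to 0.0588 and Lars2 from -0.997 to 1.081 with each library left out. The cause of these changes was not tested. Depth limits the genes with few reads, such as Zfp965, H4c1 and H4c8, and the simulated test recovered 23.4% of genes with the smallest planted change.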

Other observations

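The tests on the first principal component, the surrogate variable, Sap18b, list members without a site and the count of genes in other splits were chosen after the result was seen. How the values for transcript length, Lars2, sequencing depth and Sap18b are read was also settled after they were seen. With 1 surrogate variable in the edgeR fit, 7 genes passed an adjusted p of 0.05, and 6 of them were lower with the mimic. Zbp1, Oasl2, Irf7 and Ifi204, an interferon-inducible DNA sensor, had log2 fold changes of -0.43, -0.31, -0.21 and -0.25. Siglec1, a sialic acid receptor of macrophages that interferon induces, was at -0.30 and Sdc3, a heparan sulfate proteoglycan, at -0.24. Zfp965, with 0 reads in 2 of the 3 control libraries, was higher, at 4.23, a value that rests on 3.02 estimated reads in the other. Of the 54 interferon-stimulated genes, 41 had an unadjusted p under 0.05 in this fit, all lower, and 39 passed when adjusted over the list alone. Camera's adjusted p for the list in this fit was 0.154 with an estimated correlation. The fit has 3 residual degrees of freedom, and the variable was estimated from the same libraries.

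Few reads came from the interferon genes themselves. Of 20 interferon ligand genes in the table, 18 had 0 estimated reads over the 6 libraries together, which allows up to 0.0179 CPM each (3 counts, counting error only), and Ifnb1 had 4 reads in total.

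For the lower interferon-stimulated list, the library axis is argued against as the whole cause, since the list did not pass along that axis (camera adjusted p 0.255). Its median log2 fold change along the axis was -0.02. The list's median for the mimic stayed at -0.16 (-0.1563) with 1 surrogate variable. That variable correlated with the group at only 0.214, which limits how far it could move the median. A bias of transcript length or GC content is argued against as well: 0 of 10000 lists matched on expression, transcript length and GC content had as low a median. Over 11155 genes the mimic's fold changes tended to fall with GC content (Spearman rho -0.349) and to rise with transcript length (rho 0.156). The other lists were not matched in this way. Whether the mimic lowers the interferon-stimulated genes or the control strand raises them cannot be told apart, because 0 libraries lie outside the 2 transfected groups.

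What causes the axis that splits mimic 1, negative control 1 and mimic 3 from the other libraries stays open, and no biological explanation of it was tested. Transcript length is argued against as the whole cause: of 2231 genes with transcripts of middle length 442 were called on the axis, against a mean of 485.6 in 1000 random sets of as many genes, a fall of 8.98% (2.00% to 15.3% over the middle 95% of sets), and a part through length (Spearman rho 0.228) or GC content (rho -0.41) stays open. Sequencing depth stays open, since only mimic 2 breaks the order of the totals between the sides (difference in means -3.23 megareads). So does carried-over ribosomal RNA, for which Lars2 was taken as an assumed marker, since only negative control 3 breaks the order of Lars2 (a difference of -1.40 in mean log2 CPM). Grouping the libraries this way called 2469 genes, a structure of the samples that the component used to choose the sides already shows, and ribosomal protein genes were the list with the smallest p along it (median -0.17).

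For Sap18b, reads shared with Sap18 and a real loss could not be told apart. The summed CPM of both genes was 13.03 ± 1.11 with the mimic and 14.1 ± 2.28 with the control (SD, n = 3 each), a log2 difference of -0.107 (exact permutation p 0.6). A fall of Sap18b alone would move the sum by only -0.259, and 98.8% of the words of Sap18b occur in Sap18.

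The mimic's seed gave no sign of direct silencing in 3' UTRs, with a difference of 0.00848 in mean log2 fold change between genes with and without a site. As a direct source of the lower interferon-stimulated list, 7-base 3' UTR sites are argued against for the 51 searched members that have none. This follows from how the 51 were picked and is no test of silencing. Their mean log2 fold change was -0.16 (-0.1615, SD 0.125), so the list was lower outside the members with a site. Such sites stay open for Ifit2 and Eif2ak2, which have a site and differed from the others by 0.0671 (permutation p 0.395). Matches of 6 bases, which Zbp1 has in its 3' UTR, and sites in coding sequence were not compared within this list.

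The 6 libraries can be parted 3 against 3 in 10 ways, too few for a share under 0.05. The real grouping called 0 genes, and the highest of the others called 2469. Any grouping reaches a count of 0, so that 10 of the 10 gave as many says nothing about chance. It called 6 gene lists, where the highest of the others called 10, and 4 of the 10 gave as many. For the interferon-stimulated list the -log10 of camera's p was 40.1 in the real grouping and 9.84 in the highest of the others, so 1 of the 10 gave as small a p.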
